A study of Mus musculus with 12 samples.

How the data were processed

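Total RNA of ovaries from FVB/N female mice at 14 dpn was measured on 12 Illumina mouse bead arrays in 4 groups of 3. The groups cross presence (Tg) or absence (NoTg) of a transgene with a heterozygous (Foxo3+/-) or null (Foxo3-/-) genotype of the forkhead transcription factor Foxo3. The series title speaks of a constitutively active Foxo3 made in oocytes, and the labels give no further detail of the transgene. Per the labels, RNA was amplified to biotin-labelled cRNA by an Illumina kit.

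The deposited table of raw intensity holds 1 bead summary value per probe and array on a linear scale, not background-subtracted and not normalized. Per the file headers, the same table gives a detection p-value per probe and array; a small p-value means a signal above the negative control beads, and it moves in steps of 0.00107. A separate table of intensity normalized by the authors follows each raw column closely, and the method behind it is not given in the sources used here. That table was used only as an alternative, after taking log2; whether any scaling beyond that seen in its values was applied stays unknown. Scanner, export software and annotation version are likewise not given in the sources used here. The number of table columns without a sample is 0.

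All values below were computed from the raw intensity. limma 3.58.1 in R 4.3.3 corrected the background by the normal-exponential model, with the background level and spread taken from the detection p-values and an offset of 16, followed by quantile normalization between arrays and log2. Of 45281 probes, the 22511 detected at a p-value under 0.05 on at least 3 arrays were tested. In the annotation table given for the array, 34885 probes have 1 gene symbol, 18 have several and 10378 are unnamed here; 34807 were matched through their gene identifier to a RefSeq table of assembly GRCm38.p6 and 0 symbols changed. That assembly was used only for names and for which genes neighbour each other, since the array's own build is not named. A gene with several tested probes is represented by the brightest, which gave 12173 genes.

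One linear model with a mean per group was fitted to all 12 arrays with lmFit and eBayes with an intensity trend. The 5 comparisons are the transgene effect within each Foxo3 genotype, the effect of the null against the heterozygous genotype within each transgene state, and the interaction. Genes are described as called, risen or fallen when limma's adjusted p (Benjamini-Hochberg over probes, two-sided) was under 0.05. Fold changes carry the standard error (SE) of log2 from the model. Where a probe was detected on no array of the lower group, the fold is a bound, "at least N-fold", set against the higher of the dim value and the lowest normalized value among detected probes of each array.

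The 21 gene lists, the model of each comparison, the alternatives and the rule for named genes were written before the data were examined. The rule takes Foxo3 by every probe, the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, the 5 smallest p-values where none is called, and up to 4 members of each list by smallest p. Which of those list members are printed was chosen after the results were seen, mostly from lists that passed. Symbols of predicted genes and clones are counted and not named unless a list holds them. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 21 lists, with camera at an estimated correlation and fry as alternatives; camera compares a list with other genes, and fry's directional p does not. Of the list symbols, 2 had no match and 2 were matched by an older name.

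The linear model was tested on simulated log2 values with the means and spreads of the real probes, independent noise and 200 changed probes. Background correction, normalization and the detection filter were not simulated. Noise shared between probes and arrays that stand apart were not simulated either, so recovery in the real data may be lower. For the null effect without the transgene, 80% of changes of 1 on the log2 scale and 28% of changes of 0.6 were recovered over 22511 probes. Each array had 20072 to 22015 probes detected, and its 90th percentile of raw intensity was 8.94 to 14.9 times its background. The number of arrays limits precision. The labels do not say that the samples are separate animals, so p-values measure the spread between these samples, which may be partly technical. No chip or hybridisation day is given in the sources used here, so neither could enter the model.

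Alternatives were no background correction, median scaling, the authors' normalized values, no filter and a stricter filter (p under 0.01 on at least 6 arrays), the replicate number as a block, only the compared groups in the fit, array weights, 1 probe per gene, no intensity trend, the mean of a gene's probes, and each array left out in turn. The array background level as a covariate was added after seeing the data.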

Results

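The arrays describe whole ovaries at 14 dpn, an age at which the first cohorts of follicles grow. FOXO3 in the oocyte is known to hold primordial follicles in their resting state. The design asks how a transgene and the loss of Foxo3 each alter ovarian RNA, and whether one changes the effect of the other. Each group has 3 arrays.

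Foxo3 itself, the gene whose genotype defines the groups, is covered by 3 probes, of which 1 was bright enough to test. Its log2 intensity was 8.06 ± 0.34 (SD, n = 3) in NoTg Foxo3+/-, 7.96 ± 0.14 in Tg Foxo3+/-, 8.43 ± 0.24 in NoTg Foxo3-/- and 8.29 ± 0.08 in Tg Foxo3-/- ovaries. It was not lower in the null groups (log2 difference 0.37 without the transgene, limma adjusted p = 0.317, and 0.33 with it, adjusted p = 0.348). The transgene groups differed from their controls by -0.09 in Foxo3+/- (adjusted p = 0.910) and -0.14 in Foxo3-/- ovaries (adjusted p = 0.851). Where this probe lies relative to the deleted part of the gene, or to the transgene's sequence, is not given, so it checks no label.

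The arrays differed in background by transgene state and, to a smaller extent, by Foxo3 genotype. Background was the median raw intensity of probes whose detection p-value placed them below the middle of the negative control beads. It was 79.4 ± 1.86 (SD, n = 6) in NoTg and 68.2 ± 3.20 (SD, n = 6) in Tg arrays, with a two-sided exact permutation p = 0.00216 over 924 assignments. Every NoTg array lay between 76.3 and 81.2, and every Tg array between 65.4 and 74.2. Background and transgene therefore cannot be separated by comparing the groups. Within each transgene state, background was also higher in every Foxo3-/- than in every Foxo3+/- array. It was 79.9 to 81.2 against 76.3 to 79.8 without the transgene, and 68.5 to 74.2 against 65.4 to 67 with it. The 2 Foxo3 comparisons thus carry a smaller background difference of the same direction.

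In Foxo3-/- against Foxo3+/- ovaries without the transgene, the zona pellucida glycoprotein genes Zp3 (1.47-fold, log2 0.55 ± 0.09 SE, adjusted p = 0.00661) and Zp1 (1.46-fold, adjusted p = 0.0206) rose. So did Dnmt1, the maintenance DNA methyltransferase (1.54-fold, log2 0.63 ± 0.09, adjusted p = 0.00382), Tle6, a member of the subcortical maternal complex (1.40-fold), and the germline transcription factor Pou5f1 (1.51-fold). Lgr5, a receptor for R-spondins (2.12-fold lower, log2 -1.08 ± 0.19, adjusted p = 0.0160), and Lgals2 (1.87-fold lower, adjusted p = 0.0160), both on the surface epithelium list, fell. The cell cycle inhibitor Cdkn1a, a FOXO target, fell by 0.74 on the log2 scale (adjusted p = 0.0365).

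Of the 22511 probes, 205 were called, 90 higher and 115 lower in the null. The largest rises were Acaa1b, a peroxisomal thiolase (2.08-fold, log2 1.06, adjusted p = 0.00557), Olfr247 (2.04-fold), Efcab6 (1.87-fold), Vil1, which encodes villin (1.82-fold), Cpne9 (1.81-fold), Cd7 (1.79-fold) and Pla2g4c (1.78-fold). Rwdd2a, Lypd3, Jazf1, Homer2 and Plcg2 rose by 1.68-fold to 1.72-fold. The largest fall was Teddm2, from a log2 intensity of 6.98 to 4.94 (adjusted p = 0.000186), and it was detected on 2 of the 3 null arrays. Spint4 was detected on no null array and was at least 2.02-fold lower (adjusted p = 0.000870). Ccl21a, a lymphoid chemokine with near-identical copies and therefore uncertain, was 2.83-fold lower (adjusted p = 0.0484). NoTg Foxo3-/- replicate 2 carried much of that fall (group SD 1.15; log2 -1.50 with it and -0.84 without it). Gng13 (2.50-fold), the kinase Aatk (2.41-fold), the tight junction gene Cldn10 (2.23-fold), Ap3b2 (2.17-fold) and the fatty acid transporter Slc27a2 (2.12-fold) also fell. Sppl2a (2.11-fold), the chloride channel Cftr (2.08-fold) and Hamp2 (2.04-fold) did too.

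Of the 21 lists, 8 were called by camera, and 2 passed with an estimated correlation on all arrays. Of 13 measured zona pellucida and oocyte-secreted genes, 2 rose and 0 fell over all probes, and 5 rose adjusted over the list alone (camera adjusted p = 7.4e-07, and adjusted p = 0.0401 with an estimated correlation, which did not pass in 7 of 12 fits with 1 array left out). Gdf9, an oocyte growth factor, differed by 0.38 on the log2 scale without passing (adjusted p = 0.0799). Of 16 surface epithelium and bursa genes, 2 fell, 9 fell adjusted over the list alone, and 15 lay below 0 (adjusted p = 1.42e-07, and adjusted p = 0.0424 with an estimated correlation, which did not pass in 10 of 12 such fits). Krt18, a keratin of simple epithelia, was lower by -0.79 (adjusted p = 0.0587). The remaining 6 calls were lost with an estimated correlation. Fry, whose directional p does not compare a list with other genes, passed 7 of the 21 lists. Of 35 maternal effect genes, 2 rose, and 12 rose and 1 fell adjusted over the list alone (adjusted p = 0.0764 with an estimated correlation). Of 27 cell cycle genes, 1 rose, the mitotic kinase Plk1 (1.54-fold), and 10 rose adjusted over the list alone (adjusted p = 0.0928 with an estimated correlation); Ccne1 differed by 0.65 (adjusted p = 0.0595). Of 17 early oocyte genes, 1 rose, and 2 adjusted over the list alone (adjusted p = 0.0928 with an estimated correlation). Of 29 FOXO targets, 1 fell, and 8 adjusted over the list alone (adjusted p = 0.0764 with an estimated correlation). Of 8 adipose genes, Lpl, the lipoprotein lipase (1.54-fold), and Scd1, a fatty acid desaturase (1.63-fold), fell (adjusted p = 0.0764 with an estimated correlation). None of 10 muscle genes was called, and 1 fell adjusted over the list alone (adjusted p = 0.312 with an estimated correlation). Among matrix genes Dcn, which encodes decorin, fell 1.35-fold (adjusted p = 0.0486). Of 24 other settings, 19 lost the call of Dcn, 15 each those of Tle6 and Scd1, 14 that of Pla2g4c, 13 each those of Ccl21a, Jazf1 and Plk1, and 12 that of Cdkn1a. Leaving out 1 array gave 35 probes (without NoTg Foxo3+/- replicate 2) to 343 (without Tg Foxo3+/- replicate 1). The authors' normalized values gave 169 higher and 19 lower, and other settings gave 16 probes (array background as a covariate, chosen after seeing the data), 47 (only the compared groups), 90 (no filter) and 746 (array weights, 358 higher and 388 lower).

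**Figure D1:**
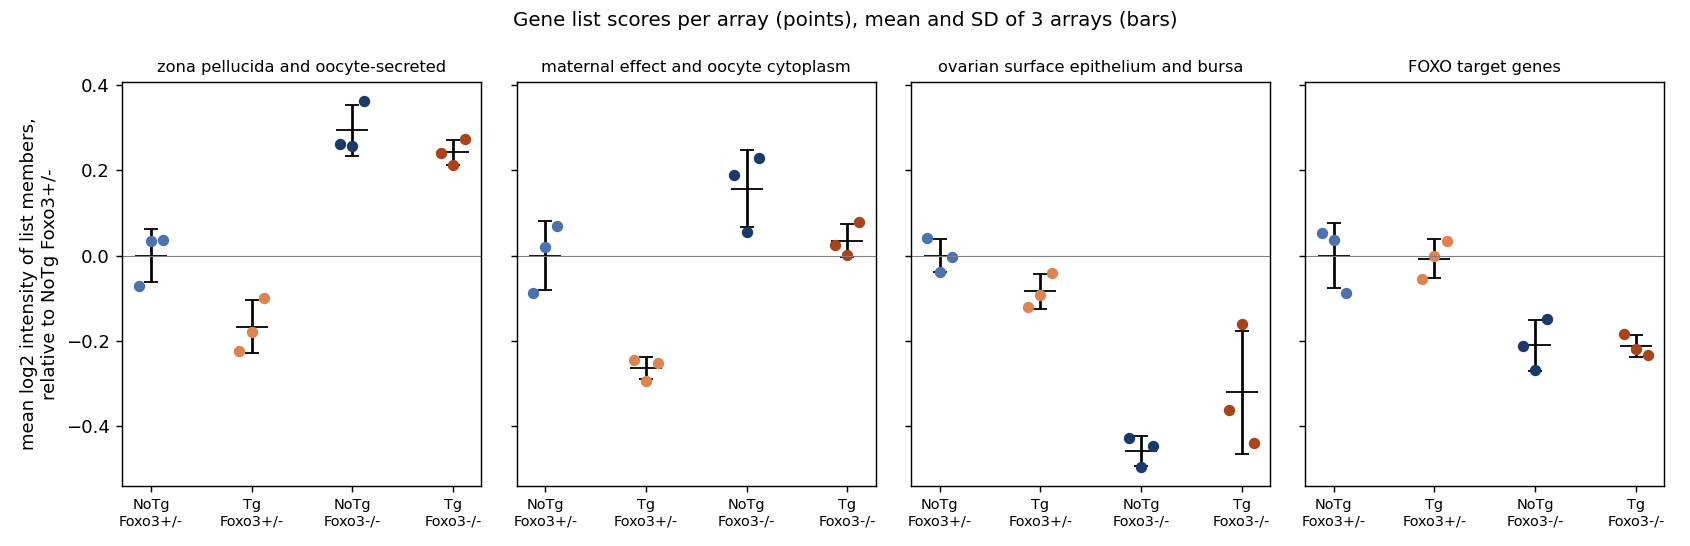
Mean log2 intensity of the members of 4 gene lists on each array (points), relative to the mean of NoTg Foxo3+/- arrays, with mean and SD of 3 arrays per group. The zona pellucida score was 0.295 ± 0.060 in NoTg Foxo3-/- and -0.167 ± 0.062 in Tg Foxo3+/- arrays, and the surface epithelium score was -0.459 ± 0.036 in NoTg Foxo3-/- arrays.

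In Foxo3-/- against Foxo3+/- ovaries with the transgene, Zp3 rose 1.83-fold (log2 0.87 ± 0.09 SE, adjusted p = 0.000118), and Zp1 1.79-fold (adjusted p = 0.000440). Izumo1r, which encodes the oocyte receptor for sperm, rose too (adjusted p = 0.00331) and was detected on 2 of 3 Tg Foxo3+/- arrays. Khdc3, of the subcortical maternal complex, rose 2.07-fold (log2 1.05 ± 0.13, adjusted p = 0.000651), Dnmt1 1.59-fold and Pou5f1 1.77-fold. The tight junction genes Cldn11 (2.11-fold) and Cldn10 (2.11-fold) fell, as did Cdkn1a (1.72-fold, adjusted p = 0.0154) and Bcl6, a transcriptional repressor among the FOXO targets (1.72-fold, adjusted p = 0.0484).

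Here 491 probes were called, 336 higher and 155 lower in the null. Further large rises were Cd7 (2.78-fold, adjusted p = 0.000365), Ninj2 (2.51-fold), Zfp541 (adjusted p = 0.00136, detected on 2 of 3 Tg Foxo3+/- arrays), Pabpn1l (2.35-fold), Acaa1b (2.29-fold), Izumo4 (2.23-fold), Efcab6 (2.19-fold), the forkhead gene Foxr1 (2.12-fold), Mvb12b (2.12-fold), Homer2 (2.07-fold) and Igfals (2.06-fold). Large falls were Teddm2 (3.30-fold, adjusted p = 0.000365), Aatk (2.85-fold), Mageb4 (2.37-fold), Pcdh9 (2.36-fold), Cacng5 (2.33-fold), Aox3 (2.29-fold), the retinoic acid binding protein gene Crabp1 (2.06-fold) and Cabs1 (1.94-fold). Spint4 and Omg were detected on no null array and were at least 1.88-fold and at least 1.63-fold lower.

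Camera called 10 of the 21 lists, and 2 passed with an estimated correlation on all arrays. Of 13 zona pellucida and oocyte-secreted genes 6 rose, Oosp2 among them (1.52-fold), and 7 rose adjusted over the list alone (adjusted p = 1.82e-08, and adjusted p = 0.0186 with an estimated correlation, which did not pass in 1 of 12 fits with 1 array left out). Of 35 maternal effect genes 11 rose, and 19 rose and 2 fell adjusted over the list alone (adjusted p = 9.48e-12, and adjusted p = 0.0314 with an estimated correlation, which did not pass in 4 of 12 such fits). Omt2a (1.62-fold) and Omt2b (1.58-fold) are close copies whose probes may share signal. Of 17 early oocyte genes, Pou5f1 and Ybx2, a germ cell RNA-binding protein gene (1.54-fold), rose, and 6 adjusted over the list alone (adjusted p = 0.0881 with an estimated correlation). Of 29 FOXO targets 3 fell, the receptor gene Tgfbr1 (1.38-fold) being the third, and 4 fell adjusted over the list alone (adjusted p = 0.0886 with an estimated correlation). Of 27 cell cycle genes Birc5, which encodes survivin, rose 1.37-fold, and it alone passed adjusted over the list alone, 1 gene (adjusted p = 0.242 with an estimated correlation). Of 16 surface epithelium genes none was called and 15 lay below 0, with Aldh1a1 at -0.48 (list adjusted p = 0.236 with an estimated correlation). Of 24 TGF-beta and BMP genes 1 fell, Tgfbr1, and 2 adjusted over the list alone (adjusted p = 0.306 with an estimated correlation); camera's call was lost in 8 of the 12 fits. Of 19 stroma genes Dcn (1.35-fold) and Pdgfra (1.54-fold) fell, and of 8 adipose genes Scd1 (1.55-fold), and camera called neither list (adjusted p = 0.0792 and 0.259). Of 16 macrophage genes 15 lay below 0, with Mrc1 at -0.54 (list adjusted p = 0.358 with an estimated correlation). Of 21 granulosa genes 18 lay below 0, with the gap junction gene Gja1 at -0.38 (list adjusted p = 0.324 with an estimated correlation). All 8 erythrocyte genes lay above 0, with Hba-a1, which has a close copy, at 0.67 (list adjusted p = 0.236 with an estimated correlation). The erythrocyte score of Tg Foxo3+/- replicate 1 was -0.844 against -0.171 and -0.200 in its group, and without that array the list median fell from 0.465 to 0.214 and camera's call was lost (adjusted p = 0.125). Without the same array the calls of the granulosa (adjusted p = 0.239) and macrophage lists (adjusted p = 0.0896) were lost too, and that of the surface epithelium list was lost without Tg Foxo3-/- replicate 3 (adjusted p = 0.0528). Of 24 other settings, 14 lost the call of Bcl6 and 12 that of Scd1. Leaving out 1 array gave 124 probes (without Tg Foxo3-/- replicate 1) to 765 (without NoTg Foxo3-/- replicate 2). Other settings gave 17 (array background as a covariate), 224 (the authors' normalized values), 283 (no filter), 774 (only the compared groups) and 2698 (array weights, 1387 higher and 1311 lower).

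Both Foxo3 comparisons, which share no arrays, overlapped. Of 90 probes higher without the transgene, 66 were also called higher with it, where independent lists would share 1.34. Of 115 lower probes, 48 were also called lower, where independent lists would share 0.792. Across the 22511 probes, which are not independent replicates, the log2 fold changes correlated at r = 0.528. Background was higher in the null arrays in both comparisons, so a shared background difference is not excluded as a source of overlap.

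**Figure D2:**
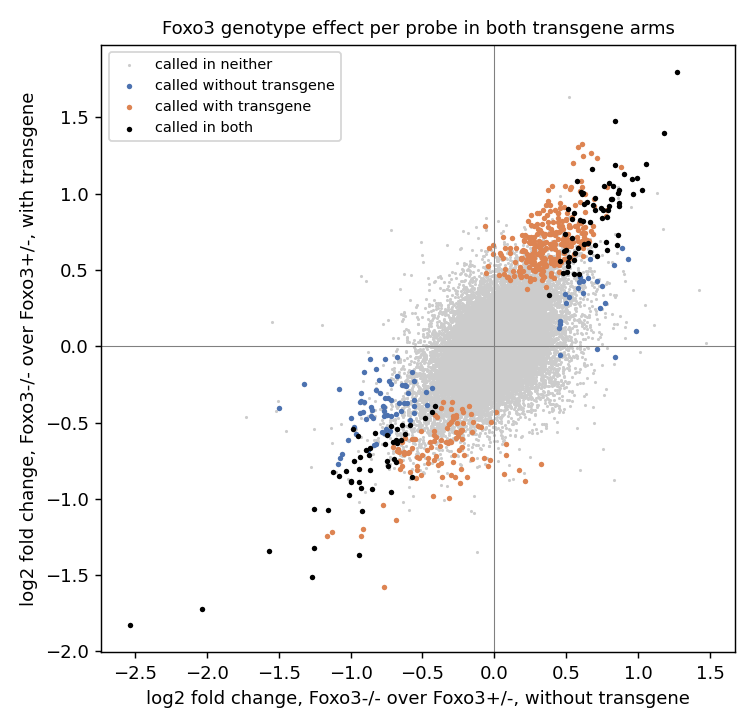
Each point is 1 of 22511 probes, with the log2 fold change of Foxo3-/- over Foxo3+/- ovaries without the transgene on the horizontal axis and with it on the vertical axis. The 66 probes higher and 48 probes lower in both (black) lie in the upper right and lower left corners.

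Of 82 probes called for the transgene in Foxo3+/- ovaries, 81 were lower with it, and with array weights 661 of 925 were. Gtsf1, a germ cell factor of the piRNA pathway, fell 2.17-fold (log2 -1.12 ± 0.15 SE, adjusted p = 0.0112). Hsp90aa1, a cytosolic chaperone, fell 2.07-fold (log2 -1.05, adjusted p = 0.0112), Stmn1, which encodes the microtubule regulator stathmin, 2.01-fold (adjusted p = 0.0311), and Syce2, of the synaptonemal complex, 1.88-fold (adjusted p = 0.0392). Slc18a2, the vesicular monoamine transporter and a member of the granulosa list, fell 1.93-fold (adjusted p = 0.0402). Mpzl1 was the only called gene that rose (1.74-fold, adjusted p = 0.0392).

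Other large falls were Golm2 (2.10-fold), the peroxisomal reductase gene Pecr (1.95-fold), the mitochondrial import receptor gene Tomm70a (1.93-fold), Xlr4c, of a family with close copies and so uncertain (1.91-fold), Ndufb9, a subunit of respiratory complex I (1.89-fold), Zfp322a (1.89-fold) and the lysosomal membrane gene Laptm4b (1.84-fold). Camera called 4 lists, all lower, and 0 held with an estimated correlation. Of 35 maternal effect genes Gtsf1 and Oas1e (1.66-fold) fell, and 9 fell adjusted over the list alone (adjusted p = 2.03e-11, but adjusted p = 0.0683 with an estimated correlation). Khdc3 stood at -0.43 (adjusted p = 0.201). Of 13 zona pellucida and oocyte-secreted genes 0 were called and 3 fell adjusted over the list alone, with Zp1 at -0.31 and Zp3 at -0.25 (list adjusted p = 0.121 with an estimated correlation). Of 13 meiosis genes Syce2 fell, and 1 rose and 3 fell adjusted over the list alone (adjusted p = 0.246 with an estimated correlation). Of 8 erythrocyte genes 7 lay below 0, with Hbb-b2, which has close copies, at -0.83 (list adjusted p = 0.287 with an estimated correlation). Without Tg Foxo3+/- replicate 1, which stood apart at an erythrocyte score of -0.844, the list median went from -0.505 to -0.198 and camera's call was lost (adjusted p = 0.198), as it was without NoTg Foxo3+/- replicate 1 (adjusted p = 0.0960). The meiosis call was lost in 3 of 12 fits with 1 array left out. Of 24 other settings, 17 each lost the calls of Slc18a2 and Oas1e, 15 each those of Syce2 and Mpzl1, 14 each those of Golm2, Tomm70a, Xlr4c, Zfp322a and Laptm4b, and 12 each those of Pecr and Ndufb9. The call count is fragile: 0 probes remained without NoTg Foxo3+/- replicate 2, without NoTg Foxo3+/- replicate 3 or without Tg Foxo3+/- replicate 2, and 0 with the authors' normalized values, with only the compared groups in the fit or with array background as a covariate. Leaving out NoTg Foxo3-/- replicate 2 gave 127, and other settings gave 21 (replicate block), 24 (no filter), 37 (1 probe per gene) and 925 (array weights, 264 higher and 661 lower).

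In Foxo3-/- ovaries the transgene effect was again mostly lower signals. Slc18a2 fell 2.51-fold (log2 -1.33 ± 0.19 SE, adjusted p = 0.0148). Trrap, a scaffold of histone acetyltransferase complexes, fell 2.17-fold (adjusted p = 0.0148), the vitamin C transporter gene Slc23a2 2.10-fold (adjusted p = 0.0114) and the RNA helicase gene Ddx3x 2.06-fold (adjusted p = 0.0146). Adh1, an alcohol dehydrogenase, rose 1.82-fold (adjusted p = 0.0457).

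Here 43 probes were called, 2 higher and 41 lower. Other falls were Ywhae (2.07-fold), Dmxl2 (adjusted p = 0.0348, detected on 1 of 3 Tg arrays), Vapa, of the endoplasmic reticulum membrane (adjusted p = 0.0329), Vhl, the substrate receptor of a ubiquitin ligase (1.93-fold), R3hdm2 (1.87-fold), the mitochondrial protease gene Pmpcb (1.83-fold), the small GTPase gene Rras2 (1.79-fold) and the nuclear pore gene Pom121 (1.78-fold). Gtsf1 stood at -0.74 (adjusted p = 0.0512). Camera called 3 lists, all lower, and 0 held with an estimated correlation. None of 35 maternal effect genes was called and 3 fell adjusted over the list alone, with Nlrp4f lower and detected on 0 of 3 Tg arrays (list adjusted p = 0.785 with an estimated correlation). None of 17 stress genes was called and 1 fell adjusted over the list alone, with the immediate early gene Egr3 lower and detected on 1 of 3 Tg arrays (list adjusted p = 0.785 with an estimated correlation). None of 16 macrophage genes was called, with Tyrobp lower and detected on 1 of 3 Tg arrays (list adjusted p = 0.785 with an estimated correlation). With 1 array left out, camera's call was lost in 5 of 12 fits for the maternal effect list, 3 for the stress list and 5 for the macrophage list, whose median was 0.00318 without NoTg Foxo3-/- replicate 2. Of 24 other settings, 16 lost the call of Adh1, 14 each those of Ywhae and Pmpcb, and 12 that of R3hdm2. The surface epithelium genes Lgr5 and Aldh1a2 stood at 0.82 and 0.57 without passing (adjusted p = 0.0832 and 0.0878). The count was 0 without NoTg Foxo3-/- replicate 1, Tg Foxo3-/- replicate 2 or Tg Foxo3-/- replicate 3 or with array background as a covariate, and 193 without NoTg Foxo3+/- replicate 3. The authors' normalized values, under which the median log2 fold change of all tested probes was -0.104 against 0.0198 here, gave 366 calls, all lower, and other settings gave 13 (1 probe per gene), 22 (no filter), 80 (stricter filter) and 512 (array weights, 47 higher and 465 lower).

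Both transgene comparisons, which share no arrays, overlapped in falls. They too share the estimate of each probe's spread, which can raise the overlap above that of independent lists. Of 81 probes lower in Foxo3+/- ovaries, 20 were also called lower in Foxo3-/- ovaries, where independent lists would share 0.148, and all 81 had the same sign. Other probes of the same genes that were not called themselves mostly did not follow. Leaving out called probes favours those that moved less. For the 34 genes that had such a probe among the brighter tested probes and detected on all 12 arrays, values were taken from the genotype not used for the call. There the called probes had a median log2 fold change of -0.70 and the other probes one of -0.01. A gene called in both comparisons was counted once for each. For 122 genes called in a Foxo3 comparison, measured in the same way and signed by the call, the medians were 0.41 and 0.28. The other probes moved by at least 0.5 of the called probes' change in 5 of the 34 genes, Ddx3x among them, and in 83 of the 122.

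**Figure D3:**
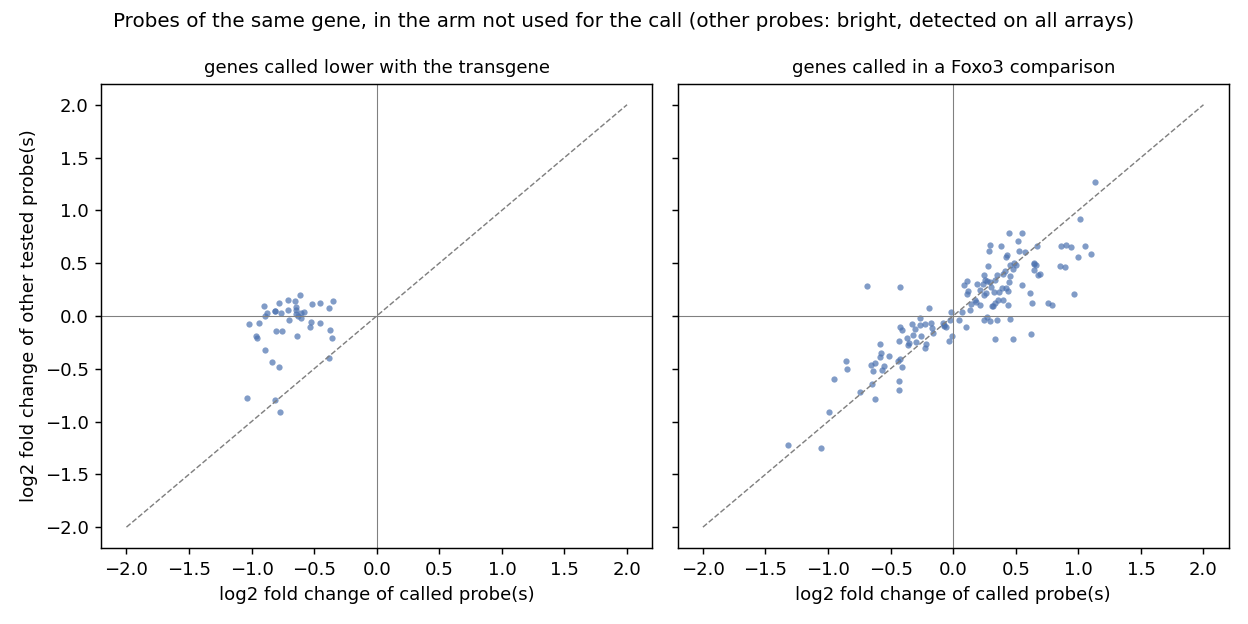
Log2 fold change of called probes (horizontal axis) and of other bright probes of the same gene (vertical axis), both from the arm not used for the call. The other probes were not called in the same comparison. A gene called in both comparisons gives a point for each. The dashed line marks equal values. For the transgene (left, 34 genes) most points lie near 0 on the vertical axis, and for Foxo3 (right, 122 genes) the other probes moved less than the called ones, at 0.691 of their median change.

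The interaction asks whether the transgene effect differed between Foxo3 genotypes. No gene was called: limma gave 0 probes, with 952 at an unadjusted p under 0.05 and a smallest adjusted p of 0.994. By smallest p, the genes were Slc7a3 (detected on 2 of 3 NoTg Foxo3+/- arrays), Josd2 at 0.72, the chemokine gene Cx3cl1 at -1.09, the glycogen synthase gene Gys1 (detected on 0 of 3 NoTg Foxo3+/- arrays) and Fbrsl1 at -0.66. Foxo3 stood at -0.05 ± 0.24 SE (adjusted p = 0.997). On simulated data with independent noise, 62% of interactions of 1 and 10% of those of 0.6 (log2) were recovered over 22511 probes. Smaller sizes were not simulated. Camera called 4 lists with 0 called members, and 0 held with an estimated correlation. The maternal effect (median log2 0.12), surface epithelium (0.19) and erythrocyte (0.69) lists were shifted upward and the macrophage list (-0.16) downward, with adjusted p = 0.358 for the first 3 and 0.511 for the last with an estimated correlation. Without Tg Foxo3+/- replicate 1 the erythrocyte median was 0.340 and camera's call was lost (adjusted p = 0.0686). The macrophage median was -0.308 to -0.0752 and the surface epithelium median 0.0997 to 0.238 with 1 array left out. There camera's call was lost in 2 of 12 fits for the maternal effect list, 3 for surface epithelium, 2 for erythrocyte and 5 for macrophage genes.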

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

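Tests of single-probe signal, background, brightness, cell shares, outside tissue and surface epithelium gene positions were chosen after the results they bear on were seen; the position of oocyte genes and the splits of the arrays were not.

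Under a test of the difference between genotypes, 4 lists passed with a preset correlation, so their transgene effects differed between Foxo3+/- and Foxo3-/- ovaries by that test alone. The median interaction was 0.117 for maternal effect genes, -0.162 for macrophage genes, 0.191 for surface epithelium genes and 0.687 for erythrocyte genes. With 1 array left out these spanned 0.0881 to 0.160, -0.308 to -0.0752, 0.0997 to 0.238 and 0.340 to 0.875, and each list lost its call in at least 2 of 12 fits. None passed with an estimated correlation (adjusted p 0.358 to 0.511), and 32 of 100 splits of the arrays called at least 4 lists, up to 9, so chance is not excluded.

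The probes called for the transgene were nearly all lower (with array weights 661 of 925 and 465 of 512) and recurred in the other genotype. Other bright probes of the same genes moved in the median by 0.0148 of the called probes' change (95% bootstrap interval over genes -0.067 to 0.142). For Foxo3 calls this ratio was 0.691 (0.585 to 0.878). Both ratios leave out probes called in the same comparison, which can lower them. The limit to bright probes was set after all other probes had given 0.0348. Closeness to background is argued against, since the called probes had a median brightness percentile of 62.4 (56.3 to 65.9). With the background level of each array as a covariate the transgene difference was -0.573 (95% interval -1.09 to -0.0564), against -0.664 without it, too wide to decide because background and transgene state go together. For the 34 genes it covers, the ratio points to a signal of single probes. Of the called genes named above for the transgene, only Ddx3x is among these, and its other probes followed. The ratio thus does not test the other named genes. A chip or bead lot that parted Tg from NoTg arrays is a candidate explanation of such a signal. An altered transcript end or isoform in transgenic oocytes is a biological one. The sources used here give no chip, so these cannot be told apart. Averaged over both genotypes 687 probes were called, and 1 of 100 splits (the real one, highest other 3) gave as many. That is the smallest share that 100 splits can give, so it argues against chance assignment of arrays without excluding it. A batch is not excluded.

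Genes of the oocyte lists called higher in Foxo3-/- ovaries are not explained by strain DNA altering genes next to Foxo3. Of the 19 called in either comparison, 0% (exact 95% interval 0 to 17.6%) lay among the 300 annotated genes on either side of it. That window holds 140 of the 12173 measured genes, so few would lie there by position alone. An effect of such DNA on genes elsewhere was not tested and stays open. A lower share of surface epithelium would raise granulosa genes alike, but with the transgene the oocyte lists gained on the granulosa list by 0.547 (95% interval over arrays 0.164 to 0.930). The gain was 0.403 (0.0325 to 0.774) without Tg Foxo3+/- replicate 1, which stood apart. Part of it was lower granulosa signal. The granulosa score was 0.111 ± 0.240 (SD, n = 3) in Tg Foxo3+/- and -0.134 ± 0.076 in Tg Foxo3-/- arrays, while the oocyte lists rose by 0.302. A change in the share of granulosa cells was not tested. Without the transgene the gain on the granulosa list was 0.246 (-0.137 to 0.629), but 0.399 (0.0413 to 0.756) without NoTg Foxo3-/- replicate 2 and 0.118 (-0.275 to 0.511) without replicate 3, so that test leaves this share open. In NoTg Foxo3-/- arrays the zona pellucida score was 0.295 ± 0.060 (SD, n = 3) and the early oocyte score 0.144 ± 0.013. Endothelium (-0.051 ± 0.015) and stroma (-0.114 ± 0.086), which a lower surface share alone would raise too, did not rise. Their SDs in NoTg Foxo3+/- arrays were 0.068 and 0.063. No other list of a non-oocyte tissue rose either, and muscle (-0.522), adipose (-0.284) and theca (-0.257) scores were lower. These scores, compared after the results were seen, argue against that share alone for the zona pellucida and early oocyte lists. A lower share of several tissues together was not tested and stays open. Averaged over both transgene states 1878 probes were called, and 1 of 100 splits (the real one, highest other 7) gave as many. Array background was also higher in the null in both transgene states, and its part in these calls stays open. More growing oocytes after loss of FOXO3 is a biological hypothesis for the genes higher with the transgene, and follicle numbers were not measured here. Relative to NoTg Foxo3+/-, the maternal effect score was -0.264 ± 0.027 (SD, n = 3) in Tg Foxo3+/- and 0.035 ± 0.039 in Tg Foxo3-/- arrays. That difference thus lay mostly in the low Tg Foxo3+/- group. The zona pellucida scores were -0.167 ± 0.062 and 0.243 ± 0.030, so that group held part of this difference too.

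Of 16 surface epithelium genes 15 lay below 0 in Foxo3-/- ovaries in both comparisons, which could come from less tissue around the ovary. Less oviduct is argued against without the transgene, where oviduct genes gained on surface genes by 0.413 (95% interval over arrays 0.146 to 0.679), and by 0.344 (0.0475 to 0.640) without NoTg Foxo3+/- replicate 2. It stays open with the transgene (0.0502, -0.216 to 0.317, and -0.0637 without Tg Foxo3+/- replicate 3). Of the 16 surface epithelium genes, 0% (exact 95% interval 0 to 20.6%) lay in the window around Foxo3. These positions are fixed by annotation and do not depend on the arrays. They speak only against strain DNA altering genes within that window, and an effect of it on genes elsewhere stays open. Less bursa or fat stays open, as the adipose genes Lpl and Scd1 fell too without the transgene, and a smaller surface relative to a larger, follicle-filled ovary is an untested biological explanation.

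For the 4 comparisons of 3 arrays with 3, 10 splits cannot give a share under 0.05. The real split gave 82 probes for the transgene in Foxo3+/- (highest other 2), 43 in Foxo3-/- (highest other 0), 205 for the null without the transgene (highest other 1) and 491 with it (highest other 1), each matched by 1 split, itself. For lists, the real and highest other counts were 4 and 8, 3 and 4, 8 and 6, and 10 and 11, with 7, 4, 1 and 2 of the 10 splits giving as many. For the interaction all 100 splits gave at least its 0 probes, and the highest other count was 687. That split exchanges the transgene labels within 1 Foxo3 genotype and so equals the averaged transgene effect, a structure of the samples. For the averaged transgene effect 70 of 100 splits gave at least its 2 lists (highest other 8), and for the averaged Foxo3 effect 16 of 100 gave at least its 8 lists (highest other 12), so chance is not excluded for these list counts.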

How the results depend on the processing

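Signal over background of 8.94 to 14.9 limits dim probes most, and the cause of a change was not tested unless named; the array background covariate was chosen after seeing the data, and a chip block was not run because no chip is given. In the order transgene in Foxo3+/-, transgene in Foxo3-/-, null without and null with the transgene, the counts of 82, 43, 205 and 491 probes became 24, 22, 90 and 283 with no filter (more probes tested), 925 (264 higher, 661 lower), 512, 746 and 2698 (1387 higher, 1311 lower) with array weights, and 0, 0, 16 and 17 with the background covariate. With only the compared groups (fewer arrays) they were 0, 47 and 774 for all but the transgene in Foxo3-/-. The authors' normalized values gave 0, 366 and 224 for all but the null without the transgene, where 188 probes were 169 higher and 19 lower against 90 and 115. With 1 probe per gene (fewer probes) both transgene counts were 37 and 13, and the stricter filter gave 80 for the transgene in Foxo3-/-. The replicate block gave 21 for the transgene in Foxo3+/- and moved no other count by over 1.5 times. Whether same-numbered arrays pair stays open. Of 18 same-numbered pairs 6 correlated over 0.1, with a median r of 0.0257 against -0.0401 for pairs of different numbers. Of 12 arrays 6 correlated best with their own number. Leaving out NoTg Foxo3+/- replicates 1, 2 and 3 gave 70, 0 and 0 for the transgene in Foxo3+/-, 59, 7 and 193 for the transgene in Foxo3-/-, 60, 35 and 64 for the null without and 466, 377 and 672 for the null with it. Leaving out Tg Foxo3+/- replicates 1, 2 and 3 gave 11, 0 and 1, then 93, 8 and 27, then 343, 132 and 182, then 495, 195 and 216. Leaving out NoTg Foxo3-/- replicates 1, 2 and 3 gave 66, 127 and 68, then 0, 127 and 17, then 82, 89 and 216, then 410, 765 and 491. Leaving out Tg Foxo3-/- replicates 1, 2 and 3 gave 13, 13 and 7, then 6, 0 and 0, then 111, 141 and 130, then 124, 233 and 161. The interaction gave 0 probes under each alternative run for it, and a fit of only the compared groups does not apply since it uses all 4. Calls of lists moved for the transgene in Foxo3+/- from 4 to 2 with no filter, array weights or fry, 1 with the background covariate and 0 with an estimated correlation, and for the transgene in Foxo3-/- from 3 to 1 with the authors' values or array weights and 0 with median scaling, the stricter filter, an estimated correlation or fry. They moved for the null without the transgene from 8 to 2 with an estimated correlation, for the null with it from 10 to 2 with that, 5 with fry and 6 with the background covariate, and for the interaction from 4 to 8 with median scaling, 1 with array weights and 0 with an estimated correlation or fry. Leave-one-out list counts were 2 to 6, 0 to 4, 8 to 9, 8 to 12 and 0 to 9. For 130 named gene results, 2402 of 3110 values kept direction and side of the threshold, 664 fell short, 36 newly passed and 8 changed sign. None of the last was called there: Khdc3 for the transgene in Foxo3+/- (0.12 with the background covariate), Foxo3 for the same (0.0098 with array weights, 0.10 without NoTg Foxo3+/- replicate 3, against -0.216 without replicate 1) and Foxo3 for the interaction (0.012 with the background covariate, 0.078 without NoTg Foxo3+/- replicate 1, 0.022 without replicate 2, 0.037 without Tg Foxo3+/- replicate 3, 0.066 without NoTg Foxo3-/- replicate 3, against -0.2395 without NoTg Foxo3+/- replicate 3).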
